A study of Homo sapiens with 6 samples.

How the data were processed

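Total RNA of MHCC97H cells was sequenced in 6 libraries, 3 of a non-target control line and 3 of a DDX17 knockout line made with CRISPR/Cas9, per the labels. Samples were grouped by their labels, and the replicate numbers came from the sample titles. The authors deposited 1 table of FPKM values per gene and library. The submitters' processing notes name CASAVA 1.8, HISAT2, StringTie, edgeR and the build hg38, without the role of each tool. The annotation release, the strand setting, trimming and filters are not given in the sources used here.

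The unit was read from the values. For genes with 1 annotated transcript, FPKM times transcript length in kilobases fell on whole multiples of a step that differed between libraries. Up to 20 fragments, 99.5% to 99.7% of those values lay within 0.05 of a whole number, where chance gives 10%. The step gave the estimated fragments per library, from 5350000 in DDX17_KO replicate 2 to 14550000 in control replicate 3. The table held 58302 rows, of which 58039 had an identifier in GENCODE release 29 and 56647 the same locus there. That annotation supplied gene types, transcript lengths and GC content, and 27699 rows were at 0 in all 6 libraries.

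The tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend and Benjamini-Hochberg adjustment over 15620 genes with a mean of at least 0.5 FPKM over the 6 libraries. A fold change on this scale understates the change of low genes. Of the tested genes, 10653 were protein-coding. The threshold was an adjusted p of 0.05. Values were read with Python 3.11.15 and pandas 2.3.3. The targeted gene and 3 other genes were also compared by a two-sided exact permutation test over 20 arrangements of the 6 libraries. The tests were two-sided, and the comparison of DDX17_KO with control was the only one between groups.

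Gene lists, 40 in all with 1144 of 1148 entries matched to the table, 52 of them through the present symbol, were fixed before the data were examined. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The genes named were DDX17, DDX5, PXN and PXN-AS1, then up to 10 per direction with the largest fold change among those past the threshold, with at least 1 FPKM in the higher group, groups that did not overlap and an approved symbol. From each list the rule took up to 2 members per direction past the threshold over all genes and, where none passed, up to 2 members with the highest mean. The levels of some members of these lists are not reported here.

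In simulated data, 200 single genes and the members of 1 gene list were changed among 15620 genes, at this number of libraries and spread per gene. The test recovered 3.03% of genes changed 1 log2 unit, 67.2% of those changed 2 units and 79.1% of those changed 3 units. It made 4 false calls among the 15384 genes left unchanged. Values were drawn independently for each gene and library, without correlation between genes or a deviation shared by libraries, and genes of low level were not among the 200. The rates need not hold for the real libraries.

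Whether the replicate numbers pair the libraries was checked from the correlation across genes of deviations from the group means. It was 0.3, 0.546 and 0.214 for replicates 1, 2 and 3, each over 0.1. Control replicate 1 also correlated with DDX17_KO replicate 3, at 0.329, and control replicate 3 with DDX17_KO replicate 1, at 0.19. After a correction for GC content and transcript length the same-number values were 0.15, 0.338 and 0.11. Deviations within a group sum to 0, so the values depend on each other. They show a likeness of the libraries numbered 2 and do not settle how replicates 1 and 3 pair. Any pairing comes from these data and not from the labels, and the fit without the block, fixed in advance, stayed the reported one.

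Alternatives fixed before the data were examined were a replicate block, pseudocounts of 0.1 and 0.01, median-of-ratios scaling, quantile normalization, no filter, a mean of at least 2 FPKM, limma without the trend, robust limma, a log2 fold change of at least 1, camera on ranks or with an estimated correlation, and each library left out. When a library was left out, the genes tested with all 6 were kept; this choice was made after counts with the filter applied again had been seen, and those counts are given too. Added after seeing the data were a correction for GC content and transcript length by splines with 4 degrees of freedom in each, that correction with the block, with protein-coding genes only or without DDX17_KO replicate 2, array weights, voom on approximate fragments, protein-coding genes only, and leaving out both libraries numbered 2. Of the tested genes, 99.64% had a GC content and length. The depth limits what can be seen: 3 fragments at HBB in the shallowest library make 0.744 FPKM, a floor that covers counting error only.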

Results

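RNA sequencing compared MHCC97H cells, a human hepatocellular carcinoma line, in which the RNA helicase gene DDX17 had been targeted by CRISPR/Cas9, with cells carrying a non-target control. Each group held 3 libraries. The title of the series names splicing of the antisense transcript PXN-AS1 as the question behind the experiment, and the values used here are levels per gene, from which isoforms cannot be read. The steps between low FPKM values gave estimated depths of 12340000, 13910000 and 14550000 fragments for control replicates 1, 2 and 3. The DDX17_KO libraries were shallower, at 10620000, 5350000 and 8210000 fragments for replicates 1, 2 and 3. No label says that the libraries came from separate cultures or clones, so the p-values measure the spread between these samples, which may be technical.

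DDX17 RNA was lower in every DDX17_KO library than in every control library. DDX17 (ENSG00000100201, hg38 chromosome 22, 38483440 to 38507660) stood at 45.7, 41.4 and 43.9 FPKM in control replicates 1, 2 and 3. The DDX17_KO replicates 1, 2 and 3 held 22.4, 7.64 and 19.1 FPKM. The group means were 43.7 ± 2.11 FPKM in controls and 16.4 ± 7.76 FPKM in DDX17_KO (SD, n = 3 each). The log2 fold change was -1.48 with a standard error of 0.36 and a 95% confidence interval from -2.33 to -0.64. A two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Over all genes the limma adjusted p was 0.282, so DDX17 did not pass the threshold. Without DDX17_KO replicate 2, the library with the lowest DDX17, the log2 fold change was -1.04 and the limma adjusted p 0.0334, in a range from 0.0127 to 0.793 over 30 other settings. A CRISPR lesion need not lower the RNA of its gene, and the RNA level does not measure the protein.

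DDX5, the close paralogue of DDX17, had a mean of 14.4 ± 5.22 FPKM in controls and 26.4 ± 1.87 FPKM in DDX17_KO (SD, n = 3 each). DDX5 (ENSG00000108654, chromosome 17, 64499616 to 64508199) was higher in each DDX17_KO library than in each control library. Its log2 fold change was 0.90 with a standard error of 0.29, and its limma adjusted p was 0.351. The exact permutation test gave p = 0.1 for DDX5. Without control replicate 2, at 8.37 FPKM the lowest library, the log2 fold change was 0.57. DDX5 passed in 3 of 30 other settings, chosen after the data were seen, with adjusted p from 0.0348 to 0.793 over all of them by limma.

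PXN and PXN-AS1 overlapped between the groups. PXN, which encodes the focal adhesion protein paxillin (ENSG00000089159, chromosome 12, 120210439 to 120265771), had 13.4 ± 1.08 FPKM in controls and 10.6 ± 2.28 FPKM in DDX17_KO (SD, n = 3 each). The log2 fold change of PXN was -0.33 with a 95% confidence interval from -0.79 to 0.14, an exact permutation p = 0.2 and a limma adjusted p of 0.444. Without DDX17_KO replicate 1 it was -0.21. PXN passed as lower in 2 of 30 other settings, chosen after the data were seen, with limma adjusted p from 0.0223 to 0.851 over all of them. PXN-AS1 (ENSG00000255857, chromosome 12, 120201291 to 120213138) had 2.08 ± 0.65 FPKM in controls and 2.29 ± 0.85 FPKM in DDX17_KO (SD, n = 3 each). Its log2 fold change was 0.09 with a 95% confidence interval from -0.48 to 0.65, an exact permutation p = 0.7 and a limma adjusted p of 0.867. The direction of PXN-AS1 turned without control replicate 1, at -0.01, and without DDX17_KO replicate 2, at -0.11. It was 0.25 without control replicate 2, 0.01 without control replicate 3 and 0.24 without DDX17_KO replicate 1. The loci of PXN and PXN-AS1 overlap, and no source used here states that fragments were assigned by strand, so the fragments of this antisense pair cannot be separated with certainty.

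**Figure D1:**
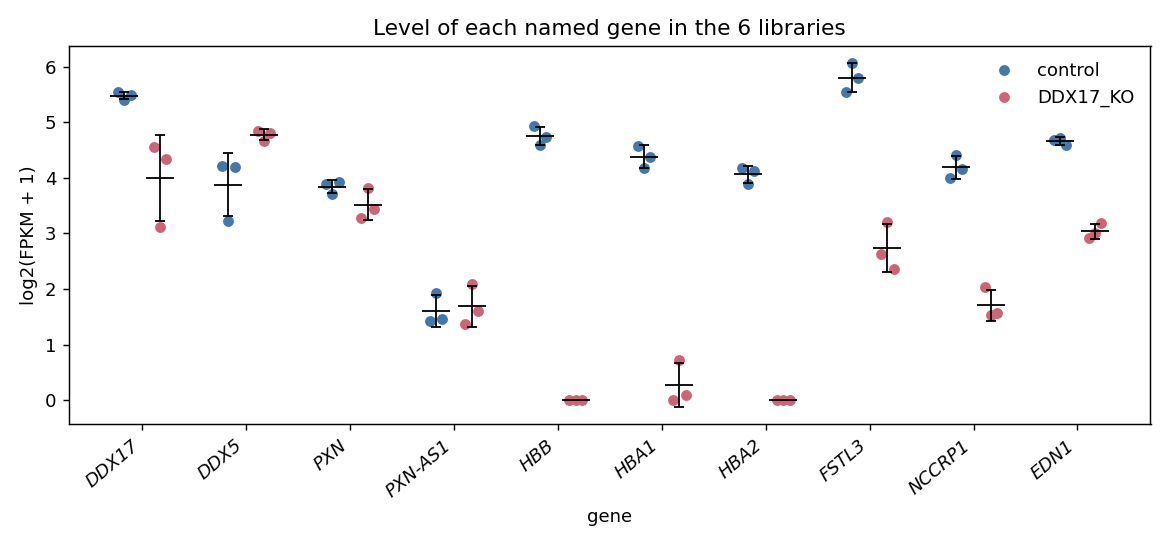
Levels of the 4 genes named in advance and the 6 genes that passed the test, as log2(FPKM + 1) on the vertical axis, with a point per library, blue for control and red for DDX17_KO, and black bars for the mean and SD of 3 libraries. HBB and HBA2 are listed at 0 in all 3 DDX17_KO libraries, and DDX17 is lowest in DDX17_KO replicate 2, at 7.64 FPKM.

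Genes that fell in DDX17_KO were the globin genes HBB, HBA1 and HBA2, and FSTL3, NCCRP1 and EDN1. HBB (ENSG00000244734, chromosome 11, 5225464 to 5229395), which encodes the beta chain of haemoglobin, stood at 29.4, 23.1 and 25.6 FPKM in control replicates 1, 2 and 3 and was listed at 0 in each DDX17_KO library, with a limma adjusted p of 8.15e-05. HBA2 (ENSG00000188536, chromosome 16, 172847 to 173710) stood at 17, 13.8 and 16.5 FPKM in the controls and was listed at 0 in each DDX17_KO library, with an adjusted p of 0.000112. HBA1 (ENSG00000206172, chromosome 16, 176680 to 177522) had 19.9 ± 2.97 FPKM in controls and 0.24 ± 0.36 FPKM in DDX17_KO (SD, n = 3 each), with an adjusted p of 0.00121 by limma. HBA1 and HBA2 encode the same alpha chain from near-identical copies, so the division of fragments between them is uncertain. Over 30 other settings the adjusted p of HBB and HBA2 ran from 3.68e-06 to 0.00524, and HBA1 lost its call with pseudocounts of 0.1 and 0.01, at up to 0.24. Transcripts typical of liver and of red cells that lay below the filter were in sum also more abundant in the controls: 25 liver transcripts summed to 1.77 FPKM in controls and 0.325 FPKM in DDX17_KO.

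FSTL3 (ENSG00000070404, chromosome 19, 676365 to 683399), a secreted binder of activins, had 55.4 ± 10.1 FPKM in controls and 5.86 ± 2.14 FPKM in DDX17_KO (SD, n = 3 each). Its log2 fold change was -3.07 with a standard error of 0.27 and a limma adjusted p of 0.013. NCCRP1 (ENSG00000188505, chromosome 19, 39196961 to 39201884) had 17.3 ± 2.71 FPKM in controls and 2.32 ± 0.67 FPKM in DDX17_KO, a log2 fold change of -2.48 with a limma adjusted p of 0.013. EDN1 (ENSG00000078401, chromosome 6, 12290363 to 12297194), the gene of the vasoconstrictor peptide endothelin 1, had 24.3 ± 1.15 FPKM in controls and 7.23 ± 0.79 FPKM in DDX17_KO. The log2 fold change of EDN1 was -1.63 with a limma adjusted p of 0.0442. With the replicate number as a block, the limma adjusted p of both NCCRP1 and EDN1 was 0.0654. Over 30 other settings FSTL3 kept its call in 19 with an adjusted p of up to 0.129, NCCRP1 in 19 with up to 0.129, and EDN1 in 13 with up to 0.342. FSTL3 had an adjusted p of 0.0596 without control replicate 1, 0.129 without control replicate 2, 0.12 without control replicate 3, 0.0603 without DDX17_KO replicate 1 and 0.0884 without DDX17_KO replicate 3. NCCRP1 had 0.0596, 0.129 and 0.12 without control replicates 1, 2 and 3 and 0.0886 without DDX17_KO replicate 3. EDN1 had 0.312, 0.258 and 0.328 without control replicates 1, 2 and 3, 0.14 without DDX17_KO replicate 1 and 0.116 without DDX17_KO replicate 3. With single libraries left out the log2 fold change ran from -3.31 to -2.88 for FSTL3, from -2.64 to -2.36 for NCCRP1 and from -1.70 to -1.56 for EDN1.

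Of 15620 genes tested with limma, 0 were higher and 6 were lower in DDX17_KO at the adjusted threshold. At an unadjusted p under 0.05 there were 2109 genes, 986 higher and 1123 lower. That count was 1600, 894 and 1172 without control replicates 1, 2 and 3, 1500, 5586 and 1215 without DDX17_KO replicates 1, 2 and 3, and 4460 with the replicate number as a block. In 3228 genes, 20.7%, the groups did not overlap. Chance gives 10% for 3 against 3 libraries that are exchangeable, a value that leaves out any pairing by replicate number. Without DDX17_KO replicate 2, 304 genes were higher and 268 lower by the same test, and without DDX17_KO replicate 1, 4 were higher and 5 lower. The counts were 0 higher and 3 lower without control replicate 1, without control replicate 2, without control replicate 3 and without DDX17_KO replicate 3. Voom on approximate fragments gave 0 higher and 5 lower.

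DDX17_KO replicate 2 and control replicate 2 stood apart from the other libraries of their groups in the same genes. Their deviations from the group means correlated at 0.546 across genes, which are not independent replicates. Spearman's rho between deviation and transcript GC content, across genes, was 0.59 in control replicate 2 and 0.539 in DDX17_KO replicate 2. In the other libraries rho was -0.539 and -0.324 in control replicates 1 and 3 and -0.418 and -0.452 in DDX17_KO replicates 1 and 3. Among genes chosen after their values were seen, FOS, an immediate early transcription factor gene, had 27.3 ± 3.34 FPKM in controls (SD, n = 3) and 1.47, 41.7 and 0.683 FPKM in DDX17_KO replicates 1, 2 and 3. NIPBL, the cohesin loader gene, had 33.4, 5.14 and 28.8 FPKM in DDX17_KO replicates 1, 2 and 3, against 5.8 ± 2.74 FPKM in controls (SD, n = 3). In both, DDX17_KO replicate 2 lay on the other side of the control mean from the other DDX17_KO libraries. It lay on the same side of that mean as the other DDX17_KO libraries in 177 of the 304 genes called higher without it and in 200 of the 268 called lower. By a stricter count, it lay above every control in 92 of the 304 and below every control in 165 of the 268. The genes were called against these same controls, and no share expected by chance was computed. The counts thus do not show that DDX17_KO replicate 2 bears out the calls made without it.

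**Figure D2:**
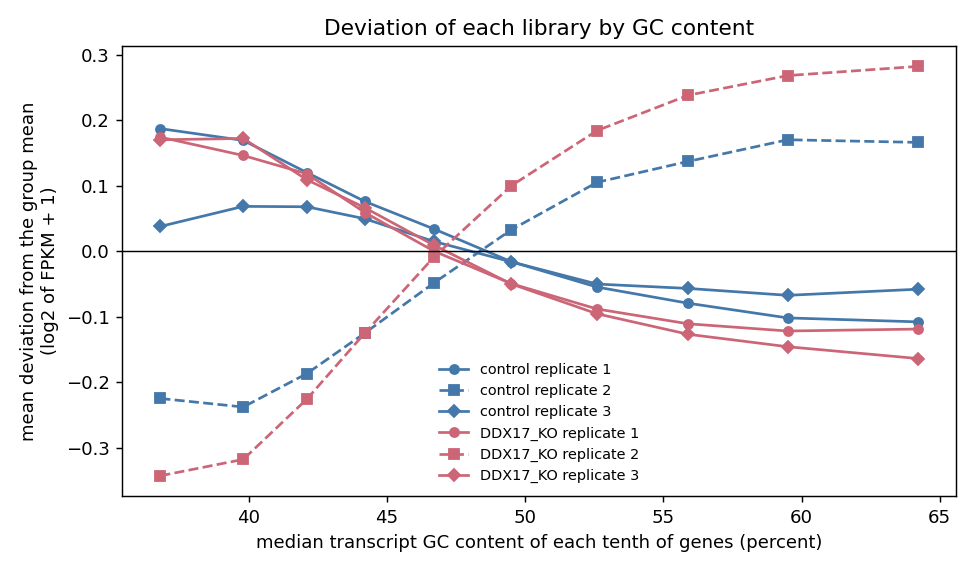
Mean deviation of each library from its group mean, in log2 units of FPKM + 1, against the median transcript GC content, in percent, of each of 10 bins of the tested genes; blue lines are control and red lines DDX17_KO libraries, and dashed lines with squares are the libraries numbered 2. In the bin with a median of 64.2% GC, control replicate 2 deviates by 0.166 and DDX17_KO replicate 2 by 0.282, while the other libraries lie below 0.

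Among 37 gene lists fixed before the data were examined and large enough to test, 13 passed camera with a preset correlation, 12 lower and 1 higher in DDX17_KO. With a correlation estimated from these libraries, 0 of the 37 passed. The estimated correlation was below the preset 0.01 in the basement membrane, fatty acid and matrix protease lists, at -0.00994, -0.0239 and -0.0482. These lists did not pass either, so their loss in this setting cannot be laid to correlation between members. Other splits of the 6 libraries, which mix the groups, gave from 0 to 11 lists by camera with the preset correlation. By fry, which asks only whether the genes of a list move on balance in 1 direction, 6 lists passed, of which 5 were among the 13. The rest of the 13 did not pass fry. Their fry adjusted p was 0.0929 for TGF-beta, 0.256 for immediate early, 0.524 for histone and 0.0757 for cholesterol genes. It was 0.0739 for G1/S, 0.511 for respiratory chain and 0.0757 for Wnt target genes, and 0.349 for long nuclear RNAs. No member of a list passed over all genes tested. Without DDX17_KO replicate 2, members were lower over all genes in several lists, with 11 immediate early, 7 TGF-beta, 5 histone and 4 mesenchymal genes. Lists that were not called also held such members, with 4 lower in the YAP and TEAD list and 4 lower beside 2 higher in the focal adhesion list. With all libraries, counts of members are given as adjusted over the list alone, and the members named by that count were chosen after their values were seen. The members named as most abundant follow the rule fixed in advance.

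TGF-beta and SMAD target genes fell as a list, with 20 of 23 tested members below 0 and a median log2 fold change of -0.47. The camera adjusted p was 3e-05, and the adjusted p was 0.543 with an estimated correlation. Adjusted over the list alone, 8 members were lower and 0 higher, against 0 over all genes. BHLHE40, a transcription factor gene, had 55.0 ± 5.63 FPKM in controls and 22.7 ± 6.37 FPKM in DDX17_KO (SD, n = 3 each). CTGF, a matricellular growth factor gene and one of the most abundant members, had 17, 116 and 23.0 FPKM in DDX17_KO replicates 1, 2 and 3 against 144 ± 14.2 FPKM in controls (SD, n = 3). ID1, the other most abundant member, had 140 ± 25.6 FPKM in controls and 126 ± 43.2 FPKM in DDX17_KO and did not pass.

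Immediate early and ERK feedback genes fell as a list, with 24 of 27 tested members below 0, a median log2 fold change of -0.52 and a camera adjusted p of 9.95e-05. The adjusted p was 0.581 with an estimated correlation. By the count adjusted over the list alone, the phosphatase genes DUSP4 and DUSP5 were lower, against 0 members over all genes. DUSP4 had 14.2 ± 0.56 FPKM in controls and 7.06 ± 1.26 FPKM in DDX17_KO (SD, n = 3 each). DUSP1 and JUNB, the most abundant members, had 443 ± 67.3 and 75.3 ± 11.1 FPKM in controls and 196 ± 204 and 40.7 ± 19.5 FPKM in DDX17_KO, and did not pass. DUSP1 stood at 76.0, 432 and 80.7 FPKM in DDX17_KO replicates 1, 2 and 3, and without replicate 2 it was lower over all genes, with a log2 fold change of -2.48 and a limma adjusted p of 0.0053. The median of the list was -0.88 without DDX17_KO replicate 2.

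Basement membrane and laminin genes fell as a list, with 13 of 16 tested members below 0, a median log2 fold change of -0.47 and a camera adjusted p of 0.000632. The adjusted p was 0.401 with an estimated correlation, and the fry adjusted p was 0.00262. Adjusted over the list alone, 5 members were lower and 0 higher, against 0 over all genes. HSPG2, the perlecan gene, had 47.7 ± 8.02 FPKM in controls and 21.5 ± 3.18 FPKM in DDX17_KO (SD, n = 3 each). LAMA5, the laminin alpha 5 gene, had 54.4 ± 10.6 FPKM in controls and 24.0 ± 4.98 FPKM in DDX17_KO. LAMC1, the most abundant member, had 83.6 ± 12.3 FPKM in controls and 80.6 ± 14.9 FPKM in DDX17_KO and did not pass.

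Lipid synthesis lists fell. In cholesterol synthesis, 21 of 24 tested members lay below 0, with a median log2 fold change of -0.32, a camera adjusted p of 0.000249 and an adjusted p of 0.552 with an estimated correlation. By the count adjusted over the list alone, 2 members were lower, against 0 over all genes. INSIG1, which encodes a regulator of sterol synthesis, was lower by that count, at 3.39 ± 0.94 FPKM in controls and 1.15 ± 0.46 FPKM in DDX17_KO (SD, n = 3 each). In fatty acid synthesis and desaturation, 14 of 19 tested members lay below 0, with a median of -0.40, a camera adjusted p of 0.00354, a fry adjusted p of 0.00262 and an adjusted p of 0.401 with an estimated correlation. Adjusted over the list alone, SCD and SREBF1 were lower, against 0 members over all genes. SCD, the stearoyl-CoA desaturase gene and the most abundant member, had 261 ± 25.7 FPKM in controls and 103 ± 12.4 FPKM in DDX17_KO (SD, n = 3 each), with a limma adjusted p of 0.088 over all genes.

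The lists of DNA replication and of histone genes fell. In G1/S and DNA replication, 28 of 35 tested members lay below 0, with a median log2 fold change of -0.30, a camera adjusted p of 0.00129 and an adjusted p of 0.552 with an estimated correlation. PCNA, the sliding clamp gene, had 160 ± 2.48 FPKM in controls and 136 ± 7.76 FPKM in DDX17_KO, and RRM1 had 151 ± 36.2 and 170 ± 23.3 FPKM (SD, n = 3 each); neither passed. Replication-dependent histone genes lay below 0 in 33 of 34 tested members, with a median of -0.44, a camera adjusted p of 0.000114 and an adjusted p of 0.694 with an estimated correlation. The estimated correlation between these members was 0.921, so they are far from independent, and the fry adjusted p was 0.524. The groups did not overlap in 1 of the 34 members. The median of the histone list was -0.77 without DDX17_KO replicate 2, and without DDX17_KO replicate 3 it was -0.17 with an adjusted p of 0.0474, in a range from 7.88e-12 to 0.0477. HIST1H1C had 826 ± 123 FPKM in controls and 746 ± 209 FPKM in DDX17_KO (SD, n = 3 each) and did not pass. Adjusted over each list alone, 0 members passed in either list, and 0 passed over all genes. Histone transcripts of this kind mostly lack a poly(A) tail and share near-identical sequence, so their division between genes is uncertain. The G2/M and mitosis list lay at a median of 0.22 with a camera adjusted p of 0.115, and with the replicate number as a block it passed at 0.0196. Its median was 0.09 without control replicate 2 and also without DDX17_KO replicate 1, and over 30 other settings its adjusted p ran from 0.0154 to 0.323. Cytosolic ribosomal protein genes lay at a median of -0.25 with a camera adjusted p of 0.0802. They passed with a block at 0.0343, without control replicate 1 at 0.0358 and without DDX17_KO replicate 2 at 0.000163 (median -0.43), in a range up to 0.883. The median was -0.02 without DDX17_KO replicate 3, with an adjusted p of 0.79, and -0.16 without control replicate 2.

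NF-kB target and acute phase genes fell as a list, with 14 of 16 tested members below 0, a median log2 fold change of -0.40, a camera adjusted p of 0.000717 and a fry adjusted p of 0.026. The adjusted p was 0.456 with an estimated correlation, and the median was -0.26 without DDX17_KO replicate 1. By the count adjusted over the list alone, TNFAIP3 and CXCL8 were lower, against 0 members over all genes. TNFAIP3, an inhibitor of NF-kB signalling, had 6.52 ± 0.28 FPKM in controls and 2.35 ± 1.21 FPKM in DDX17_KO (SD, n = 3 each).

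The mesenchymal and EMT transcription factor list fell, with 16 of 22 tested members below 0 and a median log2 fold change of -0.27. The fry adjusted p was 0.0488. The camera adjusted p was 0.0142, and it was 0.529 with an estimated correlation. Without DDX17_KO replicate 2 its adjusted p was 0.0775 at a median of -0.29, and without control replicate 2 the median was -0.16. After a correction for GC content and length its adjusted p was 0.0579, and over 30 other settings it ran from 0.00184 to 0.293. MSN, the moesin gene and its most abundant member, had 213 ± 20 FPKM in controls and 148 ± 14.3 FPKM in DDX17_KO (SD, n = 3 each) and did not pass. Adjusted over the list alone, 4 members were lower, against 0 over all genes; SNAI2, the gene of the transcription factor Slug, had 16.9 ± 1.11 FPKM in controls and 9.21 ± 1.0 FPKM in DDX17_KO (SD, n = 3 each). Matrix proteases and their inhibitors fell with 13 of 20 tested members below 0 and a median of -0.29. The fry adjusted p was 0.00101. The camera adjusted p was 0.0403, and it was 0.456 with an estimated correlation. This call was lost with a replicate block at 0.124, without DDX17_KO replicate 2 at 0.18 (median -0.27), without control replicate 1 at 0.0549 (-0.23), without control replicate 3 at 0.058 (-0.26) and after the GC and length correction at 0.131, in a range from 0.018 to 0.349. It was also lost with quantile normalization and with a mean of at least 2 FPKM. Adjusted over that list alone, 4 members were lower, including PLAUR at 9.71 ± 1.59 FPKM in controls and 5.1 ± 0.97 FPKM in DDX17_KO (SD, n = 3 each), against 0 over all genes. Wnt target genes fell with 6 of 7 tested members below 0, a median of -0.34, a camera adjusted p of 0.0403, and 0.581 as the adjusted p with an estimated correlation. The Wnt call was lost without control replicate 2 at 0.082 (median -0.24), without DDX17_KO replicate 1 at 0.0769 (-0.21), without DDX17_KO replicate 2 at 0.1 with a larger median of -0.48, and after the GC and length correction at 0.225, in a range from 0.027 to 0.455. It was lost too with quantile normalization, with no filter and with a mean of at least 2 FPKM. By the count adjusted over the list alone, 3 members were lower, led by TBX3 at 22 ± 2.82 FPKM in controls and 8.81 ± 1.68 FPKM in DDX17_KO (SD, n = 3 each), against 0 over all genes.

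The nuclear-encoded respiratory chain list fell with 32 of 38 tested members below 0, a median log2 fold change of -0.14, a camera adjusted p of 0.022 and an adjusted p of 0.723 with an estimated correlation. Adjusted over the list alone, SDHD, a subunit gene of succinate dehydrogenase, was lower at 11.2 ± 1.96 FPKM in controls and 4.27 ± 0.3 FPKM in DDX17_KO (SD, n = 3 each), against 0 members over all genes. This call was lost without control replicate 2 at 0.0752 (median -0.11), without DDX17_KO replicate 1 at 0.121 (-0.06) and without DDX17_KO replicate 3 at 0.225 (-0.09), in a range from 3.73e-06. It was lost as well with quantile normalization and with a mean of at least 2 FPKM. The median was -0.32 without DDX17_KO replicate 2. ATP5B, the most abundant member, had 160 ± 27.8 FPKM in controls and 136 ± 37.0 FPKM in DDX17_KO (SD, n = 3 each) and did not pass. Long nuclear RNAs were the list that rose, with 9 of 10 tested members above 0, a median of 0.34, a camera adjusted p of 0.019 and an adjusted p of 0.581 with an estimated correlation. That call was lost without control replicate 2 at 0.073 (median 0.21), without DDX17_KO replicate 1 at 0.0769 (0.18) and after the GC and length correction at 0.592, in a range from 0.00607 to 0.689. The median was 0.58 without DDX17_KO replicate 2. MALAT1 had 581, 179 and 337 FPKM in control replicates 1, 2 and 3 and 1394, 456 and 1213 FPKM in DDX17_KO replicates 1, 2 and 3, and NEAT1 had 60.3 ± 5.99 FPKM in controls and 93.5 ± 11.4 FPKM in DDX17_KO (SD, n = 3 each). Neither passed, and 0 members passed adjusted over the list alone.

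**Figure D3:**
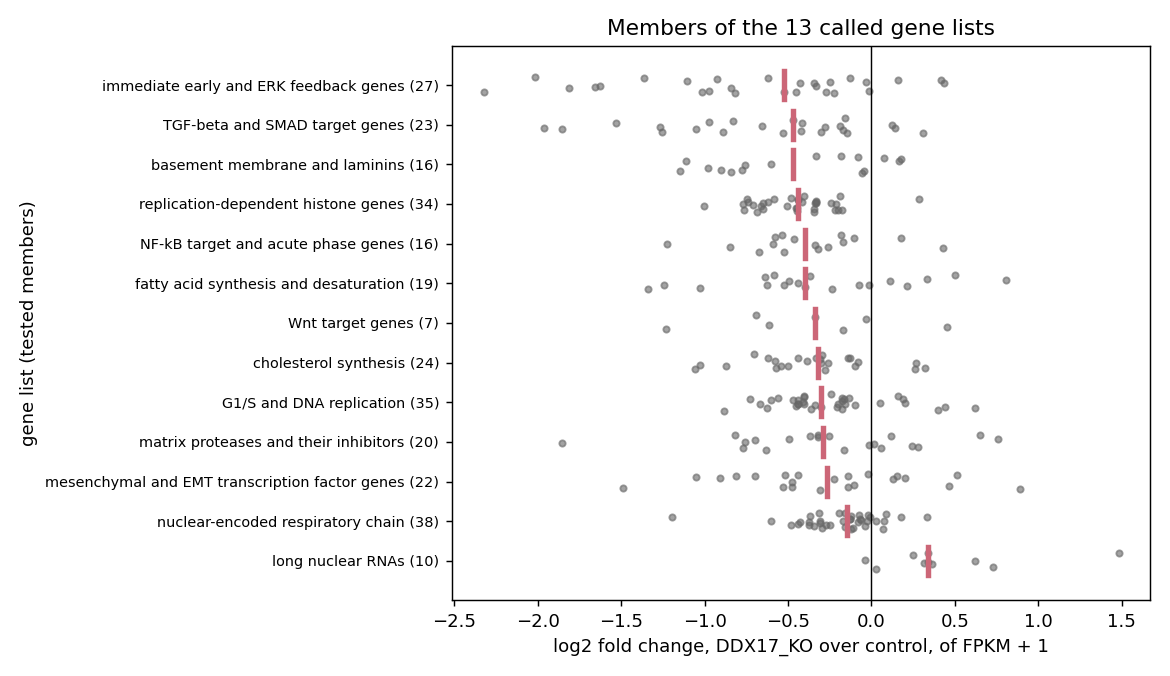
Log2 fold change of FPKM + 1, DDX17_KO over control, on the horizontal axis for each tested member of the 13 lists that passed camera with a preset correlation, with a grey point per gene and a red bar at the median of the list. The medians run from -0.52 for immediate early and ERK feedback genes to 0.34 for long nuclear RNAs, and points lie on both sides of 0 in each list.

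The other 24 lists did not pass, with camera adjusted p from 0.0547 for focal adhesion and integrin genes. The highest, 0.991, was that of hepatocyte secreted genes and of neuronal genes repressed by REST. Only 5 of 51 hepatocyte secreted members and 9 of 34 REST members were tested, so most of either list was not covered. Adjusted over the focal adhesion list alone, TNS1, ITGB4 and TNS4 were lower, against 0 members over all genes; TNS1, the tensin 1 gene, had 5.12 ± 0.91 FPKM in controls and 1.23 ± 0.29 FPKM in DDX17_KO (SD, n = 3 each). That list passed without control replicate 2 at 0.037, without DDX17_KO replicate 1 at 0.0462 and without DDX17_KO replicate 3 at 0.00671, in a range up to 0.555. Its median was -0.29 with all libraries and -0.07 without DDX17_KO replicate 2, where its adjusted p was 0.481 and 2 members were higher and 4 lower over all genes. The SR protein and hnRNP list, which holds splicing regulators, had a median log2 fold change of 0.05, which turned to -0.01 without control replicate 2, and a camera adjusted p of 0.541. The list of DDX17 paralogue and Microprocessor partners had a median of 0.24 and a camera adjusted p of 0.465. That median was 0.42 without control replicate 1, 0.00213 without control replicate 2 and 0.10 without DDX17_KO replicate 3. Interferon-stimulated genes had a median of 0.17 and a camera adjusted p of 0.204, and without DDX17_KO replicate 2 the list passed at 0.0221 with a median of 0.42 and 7 members higher over all genes, in a range from 0.000853 to 0.629. Its median was 0.09 and 0.28 without control replicates 2 and 3 and 0.07 and 0.06 without DDX17_KO replicates 1 and 3. Fibroblast and stellate cell markers passed fry, at an adjusted p of 0.0327, and not camera, at 0.342. Leukocyte, endothelial and cholangiocyte markers had 1, 2 and 4 tested members, too few for a test of the list. Adjusted over each of these lists alone, the leukocyte marker CD68 was higher and the endothelial markers ENG and EGFL7 were lower, against 0 over all genes, and with 1 member CD68 carried no adjustment. CD68 had 1.44 ± 0.19 FPKM in controls and 2.5 ± 0.7 FPKM in DDX17_KO, and ENG had 14.3 ± 2.23 and 9.22 ± 2.01 FPKM (SD, n = 3 each).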

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

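Alternatives other than the block, pseudocounts, scalings, filters, limma options, a fold minimum, camera options and single libraries left out were chosen after the data were seen. Of 13 called lists, 8 kept their call in all 30 other settings of the fit and 5 lost it in some; 13 lists not called passed in at least 1. With an estimated correlation 0 lists passed, against 13. With single libraries left out, the tested genes being kept, the count of higher genes ran from 0 to 304 and of lower genes from 3 to 268, DDX17 from -1.76 to -1.04, PXN from -0.48 to -0.21, PXN-AS1 from -0.11 to 0.25 and called lists from 11 to 16. The counts of 304 and 268 and the -1.04 came without DDX17_KO replicate 2. With the filter applied again, leaving out DDX17_KO replicate 2 gave 499 higher and 404 lower genes, DDX17 at -1.04 and PXN-AS1 at -0.11, leaving out DDX17_KO replicate 1 gave 4 higher and 5 lower genes, leaving out control replicate 1 gave 3 lower genes and PXN-AS1 at -0.00559, and leaving out control replicate 2, control replicate 3 or DDX17_KO replicate 3 gave 3 lower genes each. No filter gave 0 higher and 3 lower genes. The GC and length correction gave 1 higher and 9 lower genes, and 0 higher and 16 lower with protein-coding genes only. That correction without DDX17_KO replicate 2 gave 114 higher and 137 lower genes and DDX17 at -1.20. Protein-coding genes alone gave 1 higher and 8 lower genes. Array weights gave 1827 higher and 2034 lower genes, DDX17 at -1.11 and PXN at -0.53, both past the threshold. Without both libraries numbered 2 there were 860 higher and 516 lower genes and DDX17 at -1.075, and with the filter applied again 1018 and 614, DDX17 at -1.075 and PXN at -0.54, which passed there too. The hepatocyte secreted list passed as lower with no filter, at a median of -0.0163, a setting that admits members near 0 FPKM. The replicate block gave 0 higher and 4 lower genes and 14 lists, 12 of them among the 13, and changed no call not given with the results. For the other moved values the cause was not tested. Depths of 5350000 to 14550000 fragments limit low genes.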

Other observations

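The tests on liver and erythroid transcripts, on GC content, on depth, on the lists after correction and on 1 deviating library were chosen after the result was seen; the tests on unrelated tissues, on other splits and on the calls without DDX17_KO replicate 2 after correction were written before. The intervals around the ratios, and the ratio without a library, were added after the ratios were seen.

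Without DDX17_KO replicate 2, the interferon-stimulated genes DDX60, IFIT2, IFI44, DDX58, IFIT3, SAMD9 and OASL were higher over all genes. IFIT3 averaged 0.756 FPKM in controls and 3.55 FPKM in DDX17_KO with all libraries, where its limma adjusted p was 0.353. The interferon-stimulated list, not called as reported at 0.204, passed in 8 of 30 other settings, with adjusted p from 0.000853 to 0.629. Immediate early genes were lower without that library, among them FOSB, JUN, EGR1 and ATF3.

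HBB, HBA1 and HBA2 were present in all 3 controls and at or near 0 in all 3 DDX17_KO libraries; 3 fragments at HBB make 0.744 FPKM in the shallowest DDX17_KO library, below the lowest control value of 23.1 FPKM, which argues against lower depth. Liver transcripts below 0.5 FPKM summed to 5.46 times the DDX17_KO level in controls (bootstrap interval 2.3 to 17.7; ALB 0.306 against 0 FPKM, AMBP 0.329 against 0.0105, but HPX 0.0296 against 0.0824, with ITIH4, ORM2, CYP2E1, HP and ADH1B also higher in DDX17_KO), while 21 of the 31 liver genes are also in the fixed hepatocyte list and a liver cancer line could express them. Other erythroid transcripts summed to 4.56 times (HBG1 0.236 against 0, ALAS2 0.136 against 0), with a wide interval from 1.02 to 442, and to 27.6 times without DDX17_KO replicate 2, where HBE1 stood at 0.323 FPKM against a control mean of 0.0534. Transcripts of unrelated tissues gave 1.16, which met the outcome written before as being against RNA of such tissues. The interval, from 0.667 to 1.69, reaches past that bound, and random lists matched on mean level had a median ratio of 0.76, so this test was not taken to decide. RNA of liver or blood in the control libraries may be a source, as may a difference between the lines, and these stay open.

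Replicates numbered 2 deviated in the same genes. GC content bias could account for part, as rho with GC content was 0.539 or more in both. After the GC and length correction, 36.2% of the 572 calls made without DDX17_KO replicate 2 (207 genes) kept call and direction. Of the 572, 6 were called with all libraries too. The 572 calls had a median GC content of 40.6% in the 304 higher and 57.9% in the 268 lower genes, against 48.0% over all tested. The correction also removes any trend over GC content and length that differs between the groups, so the lost calls cannot tell bias from a real change. The correlation of the deviations stayed at 0.338 after the correction, which goes against the modelled trends as the whole source. The correction is additive and uses 1 annotated transcript per gene, so what remains cannot exclude GC content and length. Lower depth was argued against by control replicate 2, the library of rank 2 by depth in its group. A shared day or batch of the libraries numbered 2 was not tested, because no label used here gives one.

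The shifts of 13 lists were set against the same GC and length trends. After the correction 9 of 13 kept call and direction, just under the 7 in 10 named for this test as the bound of a contribution, so a contribution of the trends remains possible. The ratio of the median after the correction to that before was 0.639 at the median of the 13 lists. This goes against the modelled trends as the whole source, but an imperfect correction cannot exclude them. It also removes trends that differ between the groups, so it cannot tell bias from a real change. Among lists that kept their call, the median of immediate early genes went from -0.525 to -0.267 and that of fatty acid synthesis from -0.398 to -0.192. Only that of the respiratory chain grew, from -0.144 to -0.182. Over the 4 lists that lost their call, the same ratio was 0.343 at the median, and it differed between them. The list median went from 0.34 to 0.03 for long nuclear RNAs (MAD 0.277 and 0.195). It went from -0.27 to -0.07 for the mesenchymal list (0.486 and 0.344) and from -0.29 to -0.12 for matrix proteases (0.557 and 0.415). For Wnt targets it went from -0.34 to -0.22 (0.454 and 0.552), where the spread widened. Why each call ended was not tested. DDX17_KO replicate 2 was not the whole source, as 10 of 13 lists kept their call without it; loss of DDX17 stays among the open explanations.

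The 10 splits of the 6 libraries are too few for a share under 0.05. Of them, 1, the real one, gave 6 called genes, and the highest of the others gave 1. For lists, the real split gave 13, and the others gave 11, 10, 9, 8, 8, 6, 4, 3 and 0. Camera with the preset correlation thus also called lists in splits that mix the groups. The split with 11 placed DDX17_KO replicate 2 with control replicates 1 and 3. It also parts all 3 pairs of like number, and the other mixed splits that do so gave 6 and 4 lists.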
